A study of Mus musculus with 6 samples.

How the data were processed

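RNA of the murine breast cancer cell line Py2T was sequenced in 6 libraries, 2 per group. Per the labels, C40 cells had received 40 µM H2O2 every day for 4 months and I60 cells 60 µM. The control cells are labelled PBS with 0 µM H2O2, while the labels' treatment protocol calls them untreated. The series' design text calls the 2 libraries of a group biological duplicates. Whether these were treated apart for the 4 months is not known here. The p-values measure the spread between libraries of a group. A difference between the lines that arose without H2O2 cannot be told apart from its effect. Per the labels' protocols, total RNA was depleted of ribosomal RNA, made into libraries and read as single reads on a NextSeq instrument. The protocols describe the depletion with 2 differing kits, and which one was used is not given in the sources used here.

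Per the submitters' processing notes, STAR and the mouse genome build mm10 were used. The STAR version, the program that counted reads, its gene annotation and its strand setting are not given in the sources used here. The deposited table holds CPM (reads of a gene scaled to a common library total) as the authors computed them, with 1 row per Entrez gene and 24454 rows. Every value divided by the smallest step of its library gave a whole number within a tolerance of 0.01. Whole reads were recovered in this way for the tools that need counts. The recovered totals ran from 48113692 to 60260520 reads per library, so that 1 read equals 0.0166 to 0.0208 CPM. Gene symbols and positions came from the RefSeq annotation of GRCm38.p6 (the build also named mm10), which matched 24374 IDs. Another 5 IDs were matched through GENCODE alone and 75 stayed without a symbol. No mitochondrially encoded gene has a row (0 rows).

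Genes with at least 1 CPM in at least 2 libraries were tested, which kept 11524 and left out the rest. 6805 rows were at 0 in all 6 libraries. The test was limma 3.58.1 in R 4.3.3 with an intensity trend on log2(CPM + 0.5). It was two-sided, with all 6 libraries in 1 model of the 3 groups (3 residual degrees of freedom) and Benjamini-Hochberg adjustment over all genes tested. A call is an adjusted p below 0.05. The 3 comparisons were C40 with PBS, I60 with PBS and I60 with C40. The last is also the test of whether the effects of both lines against PBS differ.

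Before the data were examined, 31 gene lists, the named genes, the test and its alternatives were fixed. The lists cover epithelial and mesenchymal genes; NRF2 targets, peroxide and superoxide removal, ROS-generating oxidases, iron handling and ferroptosis, p53 targets and base excision repair; the integrated stress response, heat shock, cell cycle, interferon, NF-kB, TGF-beta, YAP/TAZ and matrix remodelling; cholesterol synthesis, glycolysis, hypoxia, nuclear-encoded and mitochondrially encoded oxidative phosphorylation, lysosome and xenobiotic efflux; tumour-initiating, basal and luminal markers; markers of fibroblasts, immune cells, endothelium and adipocytes; and replication-dependent histones. limma's camera tested 28 of them with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. Immune and adipocyte markers had 2 tested members each and mitochondrially encoded genes 0, too few for camera. Camera with an estimated correlation was an alternative. It tests on the 3 residual degrees of freedom of the model, so few lists can pass it whatever their correlation.

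Genes named in the text are the fixed anchors, the 6 largest rises and 6 largest falls of each comparison, and up to 4 members of each called list. The largest changes were taken among calls with at least 5 CPM in the higher group and replicates that do not overlap, leaving out predicted genes. Other members of a fixed list are named where their list is described. The values of 1 list member are not reported here. The genes of the chromosome 4 and chromosome 10 stretches were chosen after their values were seen.

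Values are given as mean ± SD of CPM with n = 2 libraries. Fold changes are those of the log2(CPM + 0.5) model. For a gene at 0 reads in a group, the fold is a lower bound against a floor of 3 reads over the group. With 1 to 3 reads, the ratio of the pooled reads is given with its exact 95% interval. These floors and intervals cover counting error only.

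The test was tried on simulated reads for 11524 genes, a part of them changed by known folds. Means came from the PBS libraries, with the real library sizes and 1 spread per gene estimated over all groups. The wider spread between the C40 replicates was thus not simulated (SD of the replicate difference 0.623, against 0.363 in PBS and 0.379 in I60). For C40 against PBS, limma called 77.3% of the genes changed 4-fold, 11.9% of those changed 2-fold and 0% of those changed 1.5-fold. For I60 against PBS the shares were 84.8%, 11.9% and 1.5%, and for I60 against C40 81.8%, 10.4% and 0%. Of 11324 unchanged genes, 4, 5 and 6 were called in the same order of comparisons. Most simulated changes of 2-fold and 1.5-fold were thus missed, and folds between 2 and 4 were not tried. In each comparison the simulation changed 67 genes 1.5-fold, 67 genes 2-fold and 66 genes 4-fold. In the data, 20.2%, 27.1% and 9.2% of the genes were called. The adjustment is stricter where fewer genes change, so the simulated shares may be too low for the data.

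Alternatives were a pseudocount of 0.1 or 1, no filter, a mean CPM of at least 5, median ratio scaling, quantile normalization, a replicate block, a fit of the 2 groups compared alone, limma without trend or robust, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, and each library left out in turn. A group left with 1 library is assumed to vary like the others. A library of the third group enters a comparison only through the spread that all groups share in the model. Leaving out rows that share reads, and leaving out the chromosome 4 stretches, were added after seeing the data. The first stretch of chromosome 4 ends at Kti12. One run, after its values were seen, ended it at Rab3b instead, with 58 tested genes in place of 57 and a median of 3.20 in place of 3.22 in I60, and the earlier end was kept.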

Results

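Gene expression was measured by total RNA sequencing in 6 libraries of Py2T, an epithelial cell line from a mouse mammary tumour. The groups were a PBS control (57141146 and 60260520 reads), the C40 line kept on 40 µM H2O2 (48113692 and 54356128 reads) and the I60 line kept on 60 µM H2O2 (53396129 and 54281136 reads), with 2 libraries each. The table holds no mitochondrially encoded genes, and 1 gene without a symbol took 1.42% to 2.52% of the counts of a library. Replicate libraries correlated across genes at r = 0.988 in PBS, 0.962 in C40 and 0.987 in I60, where genes are not independent replicates. More genes differed over 2-fold between the C40 replicates (1022) than between those of PBS (223) or I60 (217). The first principal component held 66.5% of the variance and ordered the groups PBS, C40, I60. The second held 21.6% and set C40 (-33.9 and -56.3) apart from both PBS (16.2 and 11.2) and I60 (35.1 and 27.8).

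C40 cells were compared with PBS to show how the line kept at the lower concentration differed. They had less RNA of most genes of the epithelial list and more of most genes of the mesenchymal list. Cdh1 (E-cadherin, the epithelial adhesion protein; mm10 chromosome 8, 106603350 to 106670247) fell 7.32-fold, from 533 ± 5.99 to 73.7 ± 19.9 CPM (SD, n = 2). Epcam, another epithelial adhesion protein, fell by 2.91 on the log2 scale, from 358 ± 72.6 to 47.2 ± 7.46 CPM. Vim (vimentin, the mesenchymal intermediate filament; chromosome 2, 13574311 to 13582826) rose 92.8-fold, from 29.6 ± 15.3 to 2642 ± 584 CPM. Cdh2 (N-cadherin; chromosome 18, 16588877 to 16809246) had 1 read in the PBS libraries and 76.2 ± 6.80 CPM in C40, a ratio of 8913 (95% interval 1599 to 352100).

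Of 31 measured epithelial genes, 24 fell, none rose (0) and 7 did not pass, with 27 lower when adjusted over the list alone. Their median log2 fold change was -2.18, and camera's adjusted p was 9.79e-17, with adjusted p = 0.454 with an estimated correlation. The steepest falls were in the tight junction genes Cldn7 (log2 fold change -4.52, SE 0.38), Marveld3 (-3.63, SE 0.37) and Ocln (-3.54, SE 0.27), and in the protease inhibitor Spint1 (-3.63, SE 0.29). Of 26 mesenchymal genes, 18 rose and 8 did not pass, with 21 higher when adjusted over the list alone. The median was 2.28 and camera's adjusted p 1.86e-12 (adjusted p = 0.454 with an estimated correlation). Zeb1, a repressor of Cdh1, rose 10.5-fold to 41.9 ± 3.01 CPM (limma adjusted p = 0.00226). Col3a1, a fibrillar collagen, went from 1 read in PBS to 348 ± 320 CPM, a ratio of 39240 (95% interval 7042 to 1550000), and Pdgfrb, a growth factor receptor of mesenchymal cells, rose 83.3-fold. Fn1 (fibronectin) rose 5.19-fold (limma adjusted p = 0.0183), a call lost without PBS replicate 1 or 2 (adjusted p = 0.159 and 0.0686).

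**Figure D1:**
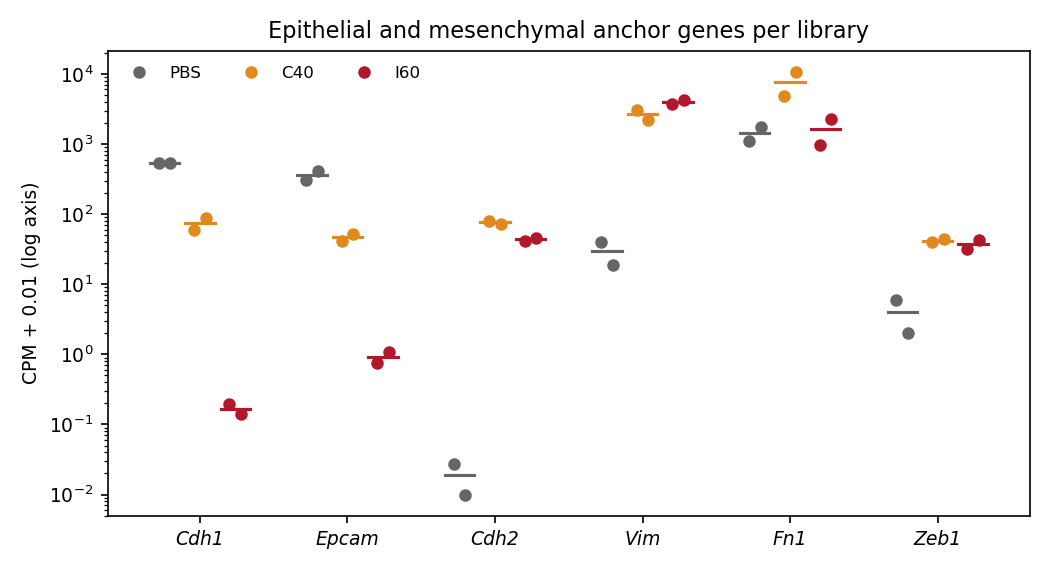
CPM plus 0.01 on a log axis of 6 epithelial and mesenchymal genes in each of the 6 libraries, with a horizontal line at each group's mean. Cdh1 stands at 533 CPM in PBS, 73.7 in C40 and 0.158 in I60, while Vim stands at 29.6, 2642 and 4026.

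Markers of fibroblasts moved with the treated lines as well: all 8 measured genes rose in C40 (8 when adjusted over the list alone; median 4.42; camera adjusted p = 1.08e-07, and adjusted p = 0.46 with an estimated correlation). 3 of the 8 also stand in another list, and collagens made up 5 of them: Col1a1, Col3a1, Col6a1, Col6a2 and Col6a3. Col6a1 rose 203-fold and Col6a2 had 1 read in PBS and 26.6 ± 23.8 CPM in C40, a ratio of 2999 (95% interval 538 to 118500). The fibroblast genes Lum, Fap and Thy1 had 0 reads in every library, and Dcn stood at 3.59 ± 0.643 CPM in C40.

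Cholesterol synthesis was lower in C40. Of 23 measured genes, 17 fell, 1 rose and 5 did not pass (18 lower and 1 higher when adjusted over the list alone). The median was -1.52 and camera's adjusted p 4.44e-07, with adjusted p = 0.808 with an estimated correlation. The C40 replicates stood apart on this list: the median of replicate 2 minus replicate 1 was -1.1 in C40, 0.286 in PBS and -0.195 in I60. Most of the 17 calls were lost with some library left out. Dhcr7, which makes the last step to cholesterol, fell by 1.85 on the log2 scale, from 529 ± 30.5 to 154 ± 66.1 CPM. Hmgcs1 fell 4.11-fold and the sterol sensor Insig1 4.32-fold, calls lost without either PBS or either I60 replicate (limma adjusted p from 0.0743 to 0.235). Hsd17b7 fell 3.65-fold, lost without PBS replicate 1 or 2 (0.134 and 0.089).

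Other lists moved less. Nuclear-encoded oxidative phosphorylation genes were higher: 6 of 30 rose, 0 fell and 24 did not pass (11 higher when adjusted over the list alone), with a median of 0.34 and camera's adjusted p = 0.00252. That call was lost without C40 replicate 1 (0.0643), and with an estimated correlation (adjusted p = 0.808 with an estimated correlation). Its leading genes Ndufa1 (2.00-fold), Atp5a1 (1.86-fold) and Ndufv1 (1.84-fold) each lost their call without PBS replicate 1 or 2 (limma adjusted p from 0.0534 to 0.123). The call of Cox5b (1.70-fold) was lost with any library but C40 replicate 2 left out (0.0858 to 0.253). Cell cycle genes were lower as a list (median -0.60, camera adjusted p = 0.00252; adjusted p = 0.808 with an estimated correlation), though 1 of 32 fell and 31 did not pass (0 when adjusted over the list alone; 8 by DESeq2 and 3 by edgeR). Without C40 replicate 1, 22 of the 32 were called lower. Without C40 replicate 2, 0 were called lower and 1 higher, and the list's adjusted p was 0.361, and the list was lower in replicate 2 than in replicate 1 of each group (medians -0.15 in PBS, -0.82 in C40 and -0.42 in I60). The 1 gene was Top2a, a topoisomerase of dividing cells (2.05-fold lower), whose call was lost with any library but C40 replicate 1 left out (0.0524 to 0.205).

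Of 12 tumour-initiating cell markers, 3 fell, 1 rose and 8 did not pass (3 and 1 when adjusted over the list alone), with a median of -0.44. Cd24a, a surface protein of epithelial cells, fell 110-fold, the intermediate filament gene Nes 22.75-fold and Ly6a (Sca-1) 5.87-fold. Itgb3, an integrin subunit, went from 1 read to 1.38 ± 1.14 CPM, a ratio of 156 (95% interval 27.5 to 6199), a call lost without either PBS or either I60 replicate (limma adjusted p from 0.0672 to 0.17). For the list, camera's adjusted p was 0.0283, with 0.168 without C40 replicate 1, 0.0591 with no filter on low values, and adjusted p = 0.46 with an estimated correlation.

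In all, limma called 1293 genes higher and 1040 lower in C40 than in PBS, of which 984 and 758 differed at least 2-fold. Among the largest rises were Ccnd2 (cyclin D2, 397-fold), the collagen chaperone Serpinh1 (331-fold), the surface protein Cd34 (313-fold) and Dpysl3 (307-fold). Among the largest falls were Rassf4 (105-fold), the necroptosis kinase Ripk3 (74.2-fold), the transglutaminase Tgm1 (59.0-fold) and Cwh43 (41.7-fold). Sfrp1, a secreted Wnt antagonist, went from 34.0 ± 1.46 CPM to 0 reads, at least 1162-fold lower. The counts were 549 and 425 without PBS replicate 1 and 607 and 545 without PBS replicate 2, and without C40 replicate 1 the count of lower genes was 1750.

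I60 cells were compared with PBS to show how the line kept at the higher concentration differed. They had lost most of the RNA of several epithelial genes, though 6 of 31 genes of the epithelial list did not pass. Cdh1 fell 811-fold to 0.158 ± 0.0412 CPM and Epcam 256-fold to 0.900 ± 0.239 CPM (SD, n = 2). Krt7, a simple epithelial keratin (chromosome 15, 101412403 to 101427806), fell 839-fold, from 3069 ± 64.4 to 3.16 ± 0.168 CPM. The keratin genes Krt8 and Krt18, tested as well, were called in neither line. Vim rose 143-fold to 4026 ± 369 CPM. Cdh2 stood at 43.5 ± 3.57 CPM against 1 read in PBS, a ratio of 5109 (95% interval 917 to 201800).

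Of these 31, 25 fell and 0 rose (26 lower when adjusted over the list alone). The median was -4.63 and camera's adjusted p 1.6e-18, with adjusted p = 0.55 with an estimated correlation. Cldn3, a tight junction protein, was down to 1 read from 278 ± 138 CPM in PBS, which was 30200 times as high (95% interval 5419 to 1193000). Esrp1, an epithelial splicing regulator, was also down to 1 read, from 242 ± 34.8 CPM, a ratio of 26080 (95% interval 4681 to 1030000). Of 26 mesenchymal genes, 16 rose, 3 fell and 7 did not pass (17 and 4 when adjusted over the list alone). The median was 2.42 and camera's adjusted p 2.5e-05 (adjusted p = 0.55 with an estimated correlation). Col3a1 reached 387 ± 43.0 CPM, a ratio of 45430 to its 1 read in PBS (95% interval 8153 to 1794000), and Col5a1 rose 74.8-fold. Zeb1 rose 9.31-fold, while Fn1, at 1613 ± 927 CPM, did not pass (limma adjusted p = 0.919). The 3 that fell lost their calls with 1 library left out. They were the transcription factor Twist2 (2.74-fold), without PBS replicate 1 or I60 replicate 2 (limma adjusted p from 0.0749 to 0.0908), and the transcription factor Prrx1 (1.88-fold) and the receptor kinase Axl (1.51-fold), without any PBS or I60 replicate (0.0874 to 0.24).

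Of 8 fibroblast markers, 7 rose and 1 did not pass (7 when adjusted over the list alone; median 4.49; camera adjusted p = 3.41e-05, and adjusted p = 0.566 with an estimated correlation). Col6a1 rose 222-fold, Pdgfrb 65.2-fold, and Col6a2 stood at 42.39 ± 10.97 CPM, a ratio of 4984 to 1 read in PBS (95% interval 894 to 196900). Dcn stood at 0.194 ± 0.116 CPM.

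**Figure D2:**
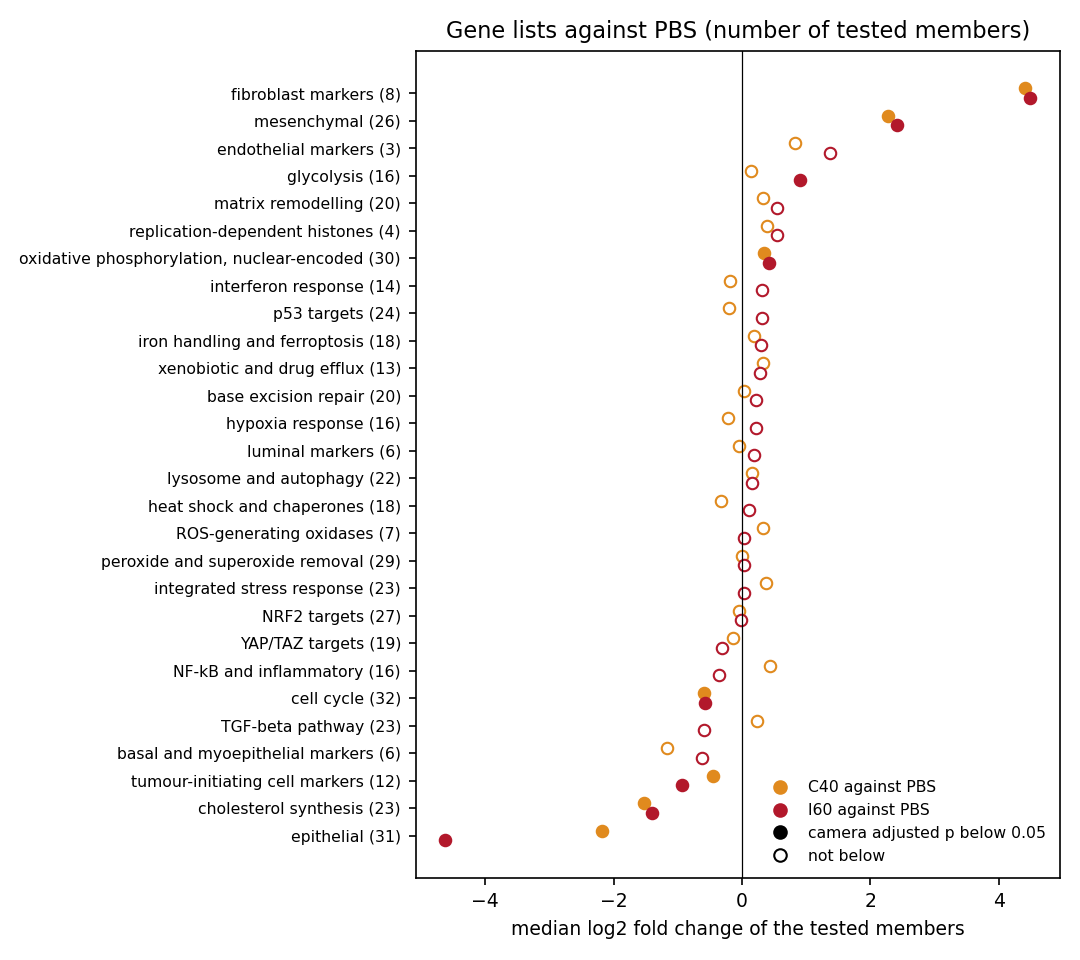
Median log2 fold change of each gene list against PBS, for C40 and I60; filled points passed camera with the preset correlation. Epithelial genes lie at -2.18 in C40 and -4.63 in I60, mesenchymal genes at 2.28 and 2.42, and none of the calls held with an estimated correlation.

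Metabolic lists changed too. Of 23 cholesterol synthesis genes, 14 fell, 1 rose and 8 did not pass (19 lower and 1 higher when adjusted over the list alone; median -1.41). Camera gave an adjusted p of 5.62e-05, with adjusted p = 0.869 with an estimated correlation. Dhcr7 fell 4.53-fold to 117 ± 6.64 CPM. Insig1 fell 4.14-fold, a call lost without either PBS or either I60 replicate (limma adjusted p from 0.108 to 0.159), and Hsd17b7 4.08-fold, lost without PBS replicate 1, PBS replicate 2 or I60 replicate 2 (0.0601 to 0.0844). Of 16 glycolysis genes, 7 rose, 0 fell and 9 did not pass (10 higher when adjusted over the list alone; median 0.90; camera adjusted p = 0.000736, and adjusted p = 0.782 with an estimated correlation). Pfkp, a phosphofructokinase, rose 10.0-fold to 430 ± 97.9 CPM and the isomerase gene Gpi1 2.29-fold. Pfkm rose 2.52-fold, lost without any PBS or I60 replicate (0.0509 to 0.063), and the hexokinase Hk1 2.16-fold, lost without PBS replicate 1, I60 replicate 1 or I60 replicate 2 (0.0511 to 0.0728).

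Of 30 nuclear-encoded oxidative phosphorylation genes, 9 rose, 0 fell and 21 did not pass (14 higher when adjusted over the list alone), with a median of 0.41. Camera's adjusted p was 0.00681 (adjusted p = 0.869 with an estimated correlation). Its examples each lost their call without 1 library: Ndufa1 (2.13-fold) without PBS replicate 2 or I60 replicate 2 (limma adjusted p = 0.0654 and 0.0642), Ndufb8 (2.07-fold) without PBS replicate 1 or I60 replicate 1 (0.0762 and 0.0671), and Cyc1 (1.86-fold) and Uqcrfs1 (1.71-fold) without PBS replicate 1, PBS replicate 2 or I60 replicate 1 (0.0507 to 0.0974). Cell cycle genes were lower as a list: 5 of 32 fell, 0 rose and 27 did not pass (0 when adjusted over the list alone), with a median of -0.57. Lower genes numbered 13 without C40 replicate 1 or 2, and 0 without PBS replicate 1 or I60 replicate 2. Camera's adjusted p was 0.0167, with 0.0795 without PBS replicate 1, 0.259 without I60 replicate 2, and adjusted p = 0.974 with an estimated correlation. E2f1, a transcription factor of S phase entry, fell 2.74-fold, a call lost without PBS replicate 1, PBS replicate 2 or I60 replicate 2 (limma adjusted p from 0.0765 to 0.0907). Tpx2 (1.85-fold lower), Top2a (1.83-fold) and Ccnb2 (1.82-fold) lost theirs without any PBS or I60 replicate (0.059 to 0.254).

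Of 12 tumour-initiating cell markers, 7 fell, 2 rose and 3 did not pass (8 and 2 when adjusted over the list alone; median -0.94; camera adjusted p = 0.0167, and adjusted p = 0.55 with an estimated correlation). Nes fell from 400 ± 18.7 CPM to 1 read, a ratio of 42990 (95% interval 7715 to 1698000), and Ly6a fell 39.1-fold. Itgb3 rose to 10.8 ± 2.76 CPM, a ratio of 1269 to 1 read in PBS (95% interval 227 to 50170), and Sox2, a stem cell transcription factor, rose 12.7-fold to 8.58 ± 1.64 CPM.

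In I60, limma called 1607 genes higher and 1515 lower than in PBS, of which 1133 and 1071 differed at least 2-fold. Ccnd2 (317-fold), Serpinh1 (312-fold), Ptprn (280-fold) and the collagen Col5a3 (236-fold) were among the largest rises. The receptor phosphatase Ptprf (730-fold) and the secreted protease Klk7 (621-fold) were among the largest falls. The counts were 771 and 740 without PBS replicate 1, 855 and 896 without PBS replicate 2, 940 and 823 without I60 replicate 1, and 756 and 815 without I60 replicate 2.

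Genes of the response to peroxide did not move as a group in either line. Of 27 NRF2 targets, 4 rose and 1 fell in C40, and 4 rose and 3 fell in I60 (5 and 1, and 4 and 3, when adjusted over the list alone). These counts rested on single libraries: in C40, 4 rose and 9 fell without C40 replicate 1, 9 rose and 1 fell without C40 replicate 2, and 1 rose and 0 fell without PBS replicate 2. In I60 the number that fell changed without a PBS replicate. It also changed without a C40 replicate, which enters this comparison only through the shared spread. By camera, adjusted p was 0.778 and 0.938, and the medians were -0.04 and -0.02, with the camera direction in C40 upward against its negative median. Nqo1, a classic NRF2 target, was at 9.07 ± 5.44 CPM in PBS, 1.76 ± 1.97 in C40 (limma adjusted p = 0.0683) and 1.13 ± 0.762 in I60 (5.71-fold lower, 0.0435). Its I60 call was lost without any PBS or I60 replicate (0.0783 to 0.256), and it was called in C40 without C40 replicate 1 (0.00588). Hmox1 (heme oxygenase) rose 1.82-fold in C40 (0.0214), lost without PBS replicate 2, I60 replicate 1 or I60 replicate 2 (0.0521 to 0.125), and did not pass in I60 (0.291). The NRF2 list was lower in replicate 2 than in replicate 1 of each group (medians -0.13, -0.57 and -0.18). Gclm, Slc7a11 and Txnrd1 did not pass in C40 (0.322, 0.955 and 0.136) or I60 (0.107, 0.981 and 0.246). Txnrd1 was called lower in C40 without C40 replicate 1 (0.0299), and Gclm lower in I60 without C40 replicate 1 or 2 (0.0353 and 0.0339). Gstp1, a glutathione transferase, rose 2.35-fold in C40 and 2.07-fold in I60.

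Of 29 genes that remove peroxide and superoxide, 3 rose and 1 fell in C40, and 6 rose and 2 fell in I60 (3 and 0, and 6 and 2, when adjusted over the list alone). The list had camera adjusted p of 0.532 and 0.534, with medians of -0.002 and 0.03, where the mean in C40 was 0.11 and so differed in sign from its median. Cat (catalase) stood at 50.2 ± 1.09 CPM in PBS, 47.6 ± 16.7 in C40 and 50.1 ± 3.17 in I60 (limma adjusted p = 0.77 and 0.993). Prdx5, a peroxiredoxin, rose 2.93-fold in C40 and Prdx6 fell 2.08-fold in I60. Prdx1 rose 6.36-fold in I60, from 462 ± 30.0 to 2938 ± 40.5 CPM; it lies in the stretch of chromosome 4 described further on, as does the oxidized-base repair gene Mutyh (9.87-fold higher). Of 20 base excision repair genes, 1 rose in C40 and 2 in I60, 0 fell in either (0 and 1 higher when adjusted over the list alone), and camera's adjusted p was 0.811 and 0.554. In C40, Mutyh rose 1.95-fold (limma adjusted p = 0.0471), a call lost with any library but C40 replicate 2 left out (0.0895 to 0.281).

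Of 24 p53 targets, 1 rose and 5 fell in C40, and 3 rose and 4 fell in I60 (1 and 6, and 4 and 4, when adjusted over the list alone), with camera's adjusted p at 0.136 and 0.749. In C40 the list was called lower without C40 replicate 2 (0.0216) and with a mean CPM of at least 5 (0.0419). Cdkn1a, the p21 inhibitor of the cell cycle, stood at 133 ± 5.60 CPM in PBS, 159 ± 61.2 in C40 (limma adjusted p = 0.603) and 239 ± 8.88 in I60 (0.0503). It was called higher in C40 without C40 replicate 1 (0.0338), and in I60 without C40 replicate 1 or 2 (0.00292 and 0.0029). Mki67, a marker of dividing cells, was at 627 ± 266, 264 ± 142 and 262 ± 25.2 CPM (0.0719 and 0.078), and was called lower in C40 without C40 replicate 1 (0.00728) and in I60 without C40 replicate 1 or 2 (0.0142 and 0.0139). Mdm2, which encodes the ligase that degrades p53, fell 14.25-fold in C40 and 12.0-fold in I60, from 3049 ± 638 to 211 ± 12.7 and 251 ± 11.8 CPM; the 7 tested genes next to it fell with it.

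Those 8 neighbouring genes on chromosome 10, 117629500 to 118889245, run from Cpm to Dyrk2 and include Mdm2, Slc35e3, Nup107, Rap1b and Mdm1. All 8 fell in both lines, with a median log2 fold change of -3.57 in C40 and -4.43 in I60. They took 1.07% of the counts in PBS, 0.0919% in C40 and 0.0596% in I60. The tested genes on either side, Cpsf6 and Cand1, did not pass in either line (limma adjusted p = 0.077 and 0.193 in C40, 0.156 and 0.421 in I60). This stretch was chosen after its values were seen, as the run of neighbours of Mdm2 called lower by at least 2 on the log2 scale in both lines.

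Another cluster lay on chromosome 4, in a pair of stretches of 2.55 and 0.79 Mb (106315980 to 108862120, from Usp24 to Kti12, and 116033002 to 116821508, from Nsun4 to Hpdl). Of their 57 tested genes, 54 rose in I60 and 1 fell, with a median log2 fold change of 3.22. In C40, 31 rose and 0 fell, with a median of 0.92, and against C40 the I60 line had 54 higher and 1 lower. The stretches took 0.367% of the counts in PBS, 0.596% in C40 and 3.03% in I60. The 22 tested genes between them had a median of -0.04 in I60. The stretches were chosen after the values were seen.

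**Figure D3:**
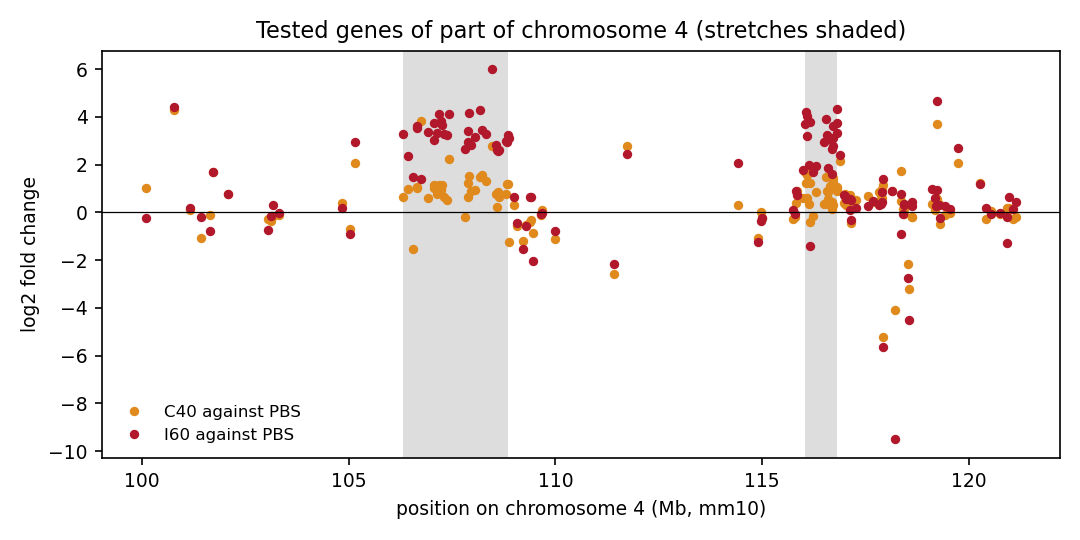
Log2 fold change against PBS of the tested genes of part of chromosome 4 by position, for C40 and I60, with the stretches from Usp24 to Kti12 and from Nsun4 to Hpdl shaded. In I60 the shaded genes have a median of 3.22 and the 22 genes between them -0.04.

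Signalling lists were not called against PBS, though single members changed. Of 23 TGF-beta pathway genes, 5 rose and 1 fell in C40, and 3 rose and 5 fell in I60 (6 and 2, and 3 and 5, when adjusted over the list alone), with camera's adjusted p at 0.218 and 0.554. Tgfb1, which encodes the ligand, rose 8.61-fold in C40 and 13.6-fold in I60, from 8.15 ± 0.368 to 74.1 ± 5.31 and 117 ± 10.3 CPM (SD, n = 2). Ltbp2, which binds microfibrils, stood at 1.08 ± 0.534, 51.79 ± 7.001 and 0.575 ± 0.151 CPM, and rose 34.1-fold in C40 alone. Of 16 NF-kB genes, 5 rose and 1 fell in C40 and 5 rose and 5 fell in I60 (6 and 3, and 5 and 5, when adjusted over the list alone). Camera's adjusted p was 0.276 in C40 (called without C40 replicate 1, 0.0285) and 0.938 in I60, where the median of -0.37 and the mean of 0.06 differ in sign. The chemokine gene Ccl2 rose 21.6-fold in C40 and 130-fold in I60. Of 19 YAP/TAZ targets, 1 rose and 4 fell in each line, though not all the same genes (1 and 5 in C40, and 1 and 4 in I60, when adjusted over the list alone; camera adjusted p = 0.66 and 0.182), with a median of -0.14 and a mean of 0.11 in C40. Of 14 interferon response genes, 3 rose and 2 fell in C40 and 6 rose and 3 fell in I60 (4 and 3, and 6 and 3, when adjusted over the list alone; camera adjusted p = 0.859 and 0.674), with a median of -0.18 and a mean of 0.10 in C40. The antigen presentation gene H2-K1 fell 6.63-fold in I60.

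No gene of the integrated stress response passed limma in either line (0 of 23; 0 at an unadjusted p under 0.05 and 0 when adjusted over the list alone; 0 by edgeR in both lines, and 0 in C40 and 1 in I60 by DESeq2; camera adjusted p = 0.296 in C40 and 0.938 in I60). Without C40 replicate 1 the C40 list was called higher (8.6e-05), as were 9 of its 23 genes. In I60, 1 gene rose and 1 fell without C40 replicate 1 or 2. All 23 genes were higher in replicate 2 than in replicate 1 of each group. Of 18 heat shock genes, 0 rose and 1 fell in C40, and 1 rose and 1 fell in I60 (0 and 0, and 1 and 0, when adjusted over the list alone; camera adjusted p = 0.203 and 0.871; 0.0285 in C40 without C40 replicate 1). Hspb1 rose 5.03-fold in I60. Of 7 ROS-generating oxidases, 2 rose in C40 and 1 rose and 1 fell in I60 (2 and 1, and 2 and 1, when adjusted over the list alone; camera adjusted p = 0.257 and 0.871). Nox4, which makes H2O2, rose 5.13-fold in C40 to 2.59 ± 0.108 CPM and stood at 0.120 ± 0.0905 CPM in I60. Of 18 iron and ferroptosis genes, 2 rose and 2 fell in each line (3 and 2 in C40, and 2 and 1 in I60, when adjusted over the list alone; camera adjusted p = 0.639 and 0.752). The iron exporter Slc40a1 rose 5.23-fold in C40 and the ferroptosis suppressor Aifm2 2.29-fold in I60. Of 16 glycolysis genes, 2 rose in C40 (2 when adjusted over the list alone; camera adjusted p = 0.475).

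Of 16 hypoxia genes, 0 rose and 3 fell in C40, and 3 rose and 1 fell in I60 (0 and 2, and 3 and 1, when adjusted over the list alone; camera adjusted p = 0.276 and 0.749). P4ha1, a collagen hydroxylase, rose 2.90-fold in I60. Of 22 lysosome genes, 4 rose and 1 fell in C40, and 3 rose and 2 fell in I60 (7 and 1, and 3 and 2, when adjusted over the list alone; camera adjusted p = 0.218 and 0.749). Of 13 xenobiotic efflux genes, 2 rose in C40 and 4 rose and 1 fell in I60 (2 and 0, and 4 and 1, when adjusted over the list alone; camera adjusted p = 0.257 and 0.445; 0.0293 in C40 without PBS replicate 1). The drug pump gene Abcg2 rose 3.01-fold in I60. Of 20 matrix remodelling genes, 7 rose and 1 fell in C40, and 7 rose and 4 fell in I60 (8 and 1, and 8 and 4, when adjusted over the list alone; camera adjusted p = 0.186 and 0.394; 0.0203 in C40 without PBS replicate 1). The collagenase gene Mmp13 rose 17.1-fold in C40, and the metalloprotease gene Adam12 fell by 5.73 on the log2 scale in I60.

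Of 6 basal markers, 1 rose and 3 fell in C40, and 3 rose and 3 fell in I60 (2 and 3, and 3 and 3, when adjusted over the list alone; camera adjusted p = 0.65 and 0.938). The basal keratin gene Krt14 fell 54.2-fold in I60. Of 6 luminal markers, 1 fell in each line (1 when adjusted over the list alone; camera adjusted p = 0.811 and 0.938), with a median of -0.05 and a mean of 0.14 in C40. Of 4 replication-dependent histones, 0 rose in C40 and 1 in I60 (0 and 1 when adjusted over the list alone; camera adjusted p = 0.296 and 0.335, the latter 0.0113 with no filter on low values). Of 3 endothelial markers, 1 rose in C40 and 2 in I60 (2 and 3 when adjusted over the list alone; camera adjusted p = 0.198 and 0.0504). That list was called in C40 with no filter on low values (0.00767), and in I60 without PBS replicate 2 (0.0453), with a pseudocount of 1 (0.0493), median ratio scaling (0.049), no trend (0.0374) or the chromosome 4 stretches left out (0.0456). With 2 tested genes each, immune and adipocyte markers were too few for camera. Of the adipocyte markers, Pparg fell 15.4-fold in C40 and 15.3-fold in I60, while Plin4 did not pass in C40 (limma adjusted p = 0.103; 0.0379 without C40 replicate 2) and rose 3.17-fold in I60, a call lost without PBS replicate 1, PBS replicate 2 or I60 replicate 2 (0.0759 to 0.164). Of the immune markers, Csf1r fell 3.58-fold in C40, lost without PBS replicate 1 or 2 (0.0771 to 0.0868), and did not pass in I60 (0.547). The lysosomal protein gene Cd68 did not pass in C40 (0.647) and rose 4.26-fold in I60.

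Both treated lines shared many calls. 897 genes were higher in both and 795 lower in both, against 180.3 and 136.7 for independent lists, and 28 were called in opposite directions against 315. Log2 fold changes correlated across genes at r = 0.781, which are not independent replicates. In 100 simulations of unchanged groups that share a control, r averaged 0.501 and the covariance was 0.041 against 1.088 observed. At most 1 gene was called in both comparisons there. As no simulated gene changed, hardly any call was possible, so that count is no measure for the 897 and 795 shared calls. With C40 compared to PBS replicate 1 and I60 to PBS replicate 2, 372 genes were higher in both and 378 lower in both (40.6 and 35 for independent lists), 5 were opposite and r was 0.725. With the PBS replicates exchanged, these were 363 and 363 (40.7 and 33), 8, and 0.755. The fold changes of each side then rest on 1 PBS library, and no library enters the fold changes of both sides. Both fits still take their spread from the same C40 and I60 libraries, which favours genes of small spread on both sides. That can add to the excess over independent lists. A deviation common to both PBS replicates could still add to the excess over independent lists.

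I60 was compared with C40 to show where the lines differ. I60 had far less RNA of several epithelial genes than C40: Cdh1 was 111-fold lower, Epcam 34.1-fold, and Krt7 226-fold, at 3.16 ± 0.168 against 827 ± 50.4 CPM (SD, n = 2). Vim (limma adjusted p = 0.371), Zeb1 (0.871) and Cdh2 (0.0759) did not pass. Fn1 was 4.89-fold lower (0.0355), a call lost with any library but C40 replicate 1 left out (0.0577 to 0.231). Of 31 epithelial genes, 16 fell, 2 rose and 13 did not pass (19 and 2 when adjusted over the list alone; median -1.24; camera adjusted p = 1.56e-10, and adjusted p = 0.773 with an estimated correlation). The 2 that were higher in I60 were the tight junction gene Ocln, whose call was lost without I60 replicate 2 (0.0718), and Dsp (desmoplakin, 4.49-fold). Cldn3 was down to 1 read from 52.5 ± 31.9 CPM in C40, a ratio of 5802 (95% interval 1041 to 229200), and Esrp1 to 1 read from 38.8 ± 15.2 CPM, a ratio of 4244 (95% interval 761 to 167700). Of 26 mesenchymal genes, 5 were lower, 0 higher and 21 did not pass, and camera did not call the list (adjusted p = 0.192; 0.0297 without C40 replicate 2).

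Glycolysis genes were higher in I60 than in C40: 3 of 16 rose, 0 fell and 13 did not pass (8 higher when adjusted over the list alone; median 0.81; camera adjusted p = 1.4e-05, and adjusted p = 0.823 with an estimated correlation). Pfkp was 3.07-fold higher, lost without I60 replicate 2 (limma adjusted p = 0.0956). Hk1 was 2.36-fold higher, lost without I60 replicate 1 or 2 (0.09 and 0.0988), and Pfkm 2.35-fold, lost without any PBS or I60 replicate (0.0653 to 0.164). Of 24 p53 targets, 2 rose, 0 fell and 22 did not pass (3 higher when adjusted over the list alone; median 0.44; camera adjusted p = 0.00394, and adjusted p = 0.773 with an estimated correlation). They were Sulf2, an enzyme that trims heparan sulfate (22.1-fold), and the death receptor Tnfrsf10b (3.07-fold). Heat shock genes were called higher as a list (median 0.26, camera adjusted p = 0.0174; adjusted p = 0.823 with an estimated correlation), with 1 of 18 higher, 0 lower and 17 not passing (1 when adjusted over the list alone). That was Hspb1, a small heat shock protein (3.31-fold). The list's call was lost without C40 replicate 2 (0.319) or I60 replicate 1 (0.429).

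In this comparison limma called 404 genes higher and 660 lower in I60, of which 370 and 566 differed at least 2-fold. The largest rises were in Tbkbp1 (49.2-fold), Podxl (podocalyxin, 44.9-fold), Arhgdib (42.2-fold), Adgre5 (40.1-fold), the proteoglycan Gpc4 (23.2-fold) and Sulf2. Large falls included S100a14 (88.2-fold) and the laminin chain Lama3 (77.9-fold). Of the fixed anchors, Nqo1, Hmox1, Gclm, Slc7a11, Txnrd1, Cat, Cdkn1a and Mki67 did not pass (limma adjusted p from 0.146 to 0.984), though Cdkn1a was called higher without C40 replicate 2 (0.00898). Higher genes numbered 832 without C40 replicate 1, 202 without I60 replicate 1 and 140 without I60 replicate 2. Lower genes numbered 411 without PBS replicate 1, 413 without PBS replicate 2, 249 without I60 replicate 1 and 280 without I60 replicate 2.

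The remaining lists were not called between I60 and C40. Camera's adjusted p was 0.0802 for the TGF-beta pathway, YAP/TAZ targets and hypoxia, all called under some other settings. The TGF-beta pathway was called lower without C40 replicate 2 (0.00747) or I60 replicate 2 (0.0289) and with a replicate block (0.0268), YAP/TAZ targets lower without C40 replicate 1 (0.039) and with the block (0.0355), and hypoxia higher without C40 replicate 2 (0.00853). Adjusted p was 0.187 for endothelial markers, 0.192 for NF-kB (0.00655 without C40 replicate 1) and 0.201 for lysosome genes (0.0289 without I60 replicate 2). It was 0.326 for base excision repair, 0.384 for the integrated stress response, tumour-initiating markers (0.00912 with a mean CPM of at least 5) and fibroblast markers (0.00853 without C40 replicate 2), and from 0.4 to 0.836 for the others. The direction of 3 uncalled lists turned on the C40 replicates. The integrated stress response was called lower in I60 without C40 replicate 1 (1.64e-05) or I60 replicate 2 (0.0223) and higher without C40 replicate 2 (0.0271). Cell cycle genes (0.000383 and 0.00685) and cholesterol synthesis (0.000383 and 0.0297) were called higher without C40 replicate 1 and lower without C40 replicate 2. Median and mean differed in sign for xenobiotic efflux (-0.05 and 0.17), basal markers (-0.03 and 0.01) and luminal markers (0.10 and -0.01). Ltbp2 was 48.7-fold lower in I60 than in C40, Adam12 48.3-fold, Prrx1 13.4-fold and Nox4 5.01-fold. Tgfbr3, a TGF-beta co-receptor, was 11.2-fold higher.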

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

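The test for reads shared between neighbouring genes and the test for a mixture of cells were chosen only after the results they measure were seen. Prrx1, Tnfrsf10b and Adgre5 are 3 of 28 genes called against PBS in opposite directions in C40 and I60 with a difference between both lines that passed limma. They are the ones already described or on a gene list; 9 of the 28 differed more than Prrx1. Prrx1, a mesenchymal transcription factor, was 2.83 higher on the log2 scale in C40 and 0.91 lower in I60, and I60 minus C40 was -3.745 (limma adjusted p = 0.000312). Its I60 call was lost without any PBS or I60 replicate (0.0874 to 0.24). Tnfrsf10b, a death receptor gene, was at -0.91 in C40 and 0.71 in I60, a difference of 1.616 (0.00159). Its C40 call was lost without PBS replicate 1 or 2 (0.0644 to 0.096) and its I60 call without any PBS or I60 replicate (0.078 to 0.13). Adgre5, an adhesion receptor gene, was at -1.24 in C40 and 4.09 in I60, a difference of 5.327 (0.000241).

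In I60, 54 of 57 tested genes in a pair of stretches of chromosome 4 rose, with a median log2 fold change of 3.22. Reads shared between neighbours are argued against, since 0 percent of these genes had another of them within 2% in every library. A bias of gene length or expression level would also raise genes elsewhere that match on both, and the highest median among 10000 such lists was 0.526. That argues against such a bias. The stretches were picked for their rise, so their excess over random lists was fixed in advance and is no evidence by itself. A gain of DNA copies is a candidate explanation: the 13 genes of the stretches that the filter had left out had a median log2 ratio of I60 to PBS of 3.558, against 0.125 for 3009 elsewhere. That evidence is weak. Of the 13 genes, 8 had at most 1 read in PBS, with a median of 4.093 against 3.125 for such genes elsewhere. Those with more than 1 read in PBS had a median of 2.71 against 0.036 elsewhere. However, 5 of the 13 had more reads in C40 than in I60, and Lurap1 was at -1.953. Regulation of the whole region stays open too, as DNA was not analysed here.

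All 23 tested genes of the integrated stress response were higher in replicate 2 than in replicate 1 of each group, with medians of 0.74 in PBS, 1.85 in C40 and 1.12 in I60 on the log2 scale. It was 1 of 10 lists of 28 that camera called between the replicates, with cell cycle (adjusted p = 3.54e-16), heat shock and NRF2 targets (4.98e-06 each) lower in replicate 2, and 0 held with an estimated correlation (lowest 0.625). Limma with a replicate block called 0 genes for the block over all genes (1120 at an unadjusted p under 0.05), while camera's adjusted p for the list was 1.28e-28, or 0.653 with an estimated correlation. A shift of all genes is argued against, since the list exceeded the highest of 10000 matched lists by at least 0.526 in each group. Thinning kept at least 97.6% of the difference, but it could hardly have moved values per library total. The I60 replicates had similar depth (53396129 and 54281136 reads), yet the list's median differed by 1.122, against 0.065 for all genes. In PBS the totals lay further apart (57141146 and 60260520 reads), yet the list differed less (0.739). These values argue against depth for the 23 genes in I60 and PBS. C40 had both the widest gap in reads and the largest list difference (1.847). A difference between harvests may be involved, though the labels name none and no biological explanation was tested.

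By mean CPM, 24 of 31 epithelial genes were lower in C40 than in PBS and lower again in I60, while 6, with Ocln among them, were lowest in C40. Another set of 79 genes, 13 of them on that list, was picked for its loss in I60, a choice that by itself puts C40 above I60; its median in C40 was 14.1% of PBS. A mixture of PBS-like and I60-like cells would give these 79 genes 1 common share. Yet the 95th percentile of the share was 36.4 times the 5th, and 32 genes were over 4-fold above both other groups in C40. The lowest shares, in Sfrp1 (0%), Rassf4 (0.15%) and Ripk3 (0.2%), were of genes off the epithelial list. The 13 genes on it ran from 4% (Cldn7) to 35.3% (Cldn4), so the spread over all 79 does not decide the question for epithelial genes. Fibroblasts rich in Dcn and Lum are argued against as the source of the mesenchymal transcripts, because both reached at most 4.047 CPM in any treated library. Dcn still rose in C40, from 1 read in PBS to 371 reads. Fibroblast-like cells with little of either gene stay open. That C40 cells had lost part of their epithelial program at the lower H2O2 concentration is a hypothesis that may hold, found and tested on the same data. The test covered PBS-like and I60-like cells only, so a mixture of another pair of cell states, or of more than a pair, stays open.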

How the results depend on the processing

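Leaving out rows that share reads, leaving out the chromosome 4 stretches and giving each comparison its own PBS replicate were chosen only after the results were seen. Of 122 results of named genes, 96 were called, and 68 of these kept their call under all alternatives run. The other 28 lost it in some (28 without a library, 14 under another setting), 9 were gained and 0 reversed. Of 84 list results, 19 were called and all 19 were lost with an estimated correlation, 5 also without a library. Another 20 were gained in some setting. Losses with an estimated correlation do not by themselves show that correlation between genes undoes a call, as that test has few degrees of freedom. For p53 targets in I60 against C40 the estimated correlation was 0.009, below the preset 0.01, yet camera's unadjusted p went from 0.000422 to 0.0382. Counts of genes that moved over 1.5-fold in I60 against C40 were 239 higher with a mean CPM of at least 5, and 418 lower with only the 2 groups compared and 1064 lower with DESeq2. Against PBS, a fit of the 2 groups compared alone called 961 higher and 715 lower in C40, and 2121 and 2066 in I60. The main fit, in which all groups share 1 spread, called 1293 and 1040 in C40, and 1607 and 1515 in I60. It thus called more genes in C40 and fewer in I60. Genes lower in both lines numbered 510 with a mean CPM of at least 5, where fewer genes are tested. With a PBS replicate for each comparison, shared genes numbered 372 or 363 higher and 378 or 363 lower. With 1 library left out, C40 against PBS ranged from 549 (without PBS replicate 1) to 1717 (without C40 replicate 1) higher and from 425 to 1750 lower (the same libraries). I60 against PBS ranged from 756 (without I60 replicate 2) to 2120 (without C40 replicate 2) higher and from 740 (without PBS replicate 1) to 2070 (without C40 replicate 2) lower. I60 against C40 ranged from 140 (without I60 replicate 2) to 832 (without C40 replicate 1) higher and from 249 (without I60 replicate 1) to 937 (without C40 replicate 1) lower. In I60 against C40, 3 uncalled lists reversed without C40 replicate 2, by camera's adjusted p: the integrated stress response at 0.0271 (range without a library 1.64e-05 to 0.737), cell cycle at 0.00685 (0.000383 to 0.65) and cholesterol synthesis at 0.0297 (0.000383 to 0.989). The cause was not tested. A replicate block changed 5 results of named genes and 2 of lists: in I60 against C40 it called the TGF-beta pathway (0.0268; 0.00747 to 0.823 over all alternatives) and YAP/TAZ targets (0.0355; 0.00344 to 0.773) lower. Replicate deviations correlated across genes at 0.154 (PBS and C40), 0.105 (PBS and I60) and 0.438 (C40 and I60). With 1 library left out, the number of called members moved over 1.5-fold for 73 of 93 pairs of a list and a comparison, so these counts are unstable at n = 2. limma robust gives no separate camera value. Depth limits genes near 1 read, which equals 0.0166 to 0.0208 CPM.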

Other observations

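The test of chromosome 19 was chosen only after its result was seen. Beside the chromosome 4 genes, the lines carried a fall of 8 neighbouring genes around Mdm2 on chromosome 10, with medians of -3.57 in C40 and -4.43 in I60. Mdm2 stood at 3049 ± 638 CPM in PBS (SD, n = 2), and Nup107, a nuclear pore gene of the same stretch, was lower in both lines as well. No explanation was tested for that stretch.

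Of the shared changes, 759 genes were higher in both lines and 605 lower in both without a called difference between I60 and C40. Another 180 were lower in both and lower again in I60 than in C40, and 90 were higher in both and higher again.

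Rows of the γ-protocadherin cluster hold near-identical reads: 21 of its 22 tested rows were within 2% of another in every library, and 22 were lower in I60 than in PBS. The 52 rows of this kind are therefore not independent genes. Myc differed between the C40 libraries, at 376.3 CPM in replicate 1 and 3203 CPM in replicate 2.

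Medians of whole chromosomes lay outside the range of random lists for 7 of 20 chromosomes in C40 and 13 of 20 in I60 against PBS. Chromosome 3 had medians of -0.36 and -0.26, and in I60 chromosome 1 stood at -0.26, chromosome 9 at -0.26, chromosome 18 at -0.28 and chromosome 15 at 0.23. Genes of chromosome 19 had medians of 0.34 in C40 and 0.30 in I60, and the share of 10000 random lists that reached these was 1e-04, the smallest that these draws can give.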
